A study of Caenorhabditis elegans with 4 samples.

How the data were processed

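Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where MSH-5 sits on the genome of Caenorhabditis elegans. The samples are 4 libraries from fem-2(b245) adults with a germline, grown at 20 °C: 2 libraries of MSH-5 ChIP DNA and 2 of input DNA, the sheared chromatin before immunoprecipitation. Each kind carries the replicate numbers 1 and 2. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical.

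Per the labels' protocols, frozen ground worms were crosslinked with EGS and then with EGS plus formaldehyde, the chromatin was sonicated, and DNA was recovered with an affinity-purified rabbit polyclonal antibody raised against part of MSH-5. The labels' protocols describe single-end Illumina libraries amplified by PCR, and name no molecular identifiers. Reads were aligned with BWA to ce10, per the submitters' processing notes. The file headers give the build as WormBase WS220, and every coordinate below is 1-based as deposited, with the build taken from these headers. The build was not checked against chromosome sequences, which were not used here, and the last combined peaks of III and IV, which end at 13783731 and 17493824, may run slightly past the ends of the chromosomes in that build. Read depth, read filters, BWA settings and the input library set against each ChIP library are not given in the sources used here.

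The deposited data are 3 peak lists. The list of each ChIP library was called with MACS, per the file headers and source columns, and each of its peaks has a deposited score that starts just above 50. The list of the whole series was called with MACS v2, per its source column, and is called the combined list here. Whether its reads were pooled over the replicates is not given in the sources used here. Its scores, as deposited by the authors, start at 1.33, so they are on another scale than those of the replicate lists, and the scale of neither is stated. Scores were therefore used to rank, describe or filter peaks within 1 list. The exception is a correlation of scores between the replicate lists, both called with MACS, over overlapping peaks. A score of exactly 3100 was given to 39 peaks of replicate 1 and 27 of replicate 2, which are tied. This score does not order these peaks, and 3100 in both replicate lists does not show equal enrichment. The replicate lists show what each library gave on its own, but a peak missing from a list may lie just under the caller's threshold, and no read counts stand behind a peak. Intervals therefore cover the counting of peaks only.

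Peaks were compared on the 5 autosomes and X. Mitochondrial peaks were kept out of all comparisons. The length of a chromosome was taken as the end of its last peak in any of the 3 lists. Peaks were called shared when they overlapped by at least 1 bp. Chance overlap was measured with a two-sided permutation test of 100000 circular shifts, in which all peaks of a chromosome move together by a random distance and so keep their spacing. The smallest p these shifts can give is 1e-05. The share of peaks on each chromosome was set against its share of length with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes. Chromosome arms were defined as the outer 25% of each chromosome at either side, and the share of peak midpoints there was tested with the same circular shifts. A difference in arm share between the replicates was tested by moving both lists together. For X against the autosomes of 1 list, each chromosome moved by its own random distance. Intervals of shares are exact 95% Clopper-Pearson intervals. Peaks lie in clusters, so binomial and Fisher tests, which take each peak as independent, give p-values that are too small. Spacing was compared with 1000 random placements of the peaks. No test compared conditions, because the series has a single condition, and the 2 ChIP replicates enter as separate lists.

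These definitions, the rule for named regions and the alternatives for overlap, support, X share and arm share were fixed before the data were examined. The regions named are the 10 best-scored combined peaks that overlap a peak in both replicate lists, and the best such peak of each chromosome. The tests of X among the best-scored peaks, of the arm share of X and autosomes apart and of differences between arm shares, of chromosome ends and of spacing were chosen after seeing the data, as were widths, dense windows, sharing by score and peaks found in 1 list alone. Alternatives were a reciprocal overlap of 0.5, a distance of 500 bp, the better-scored 50% of a list, peaks found in both replicates, peaks merged within 2 kb or 10 kb, a narrower centre that leaves 66.7% of the length to the arms, random placement, and each replicate's own list in place of the combined one.

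The planned counts of peaks at gene starts, in gene lists and at tRNA genes were not run, since the gene table used here is of another build (WBcel235) than the headers name, and coordinates were not moved between builds. Peaks are therefore given by position, without gene, exon or promoter labels. Input libraries were not analysed here. The shift tests of overlap and arm share were tried on simulated lists. Of 100 pairs of random lists with the widths of the real replicate lists, 4 passed 0.05 for overlap. Of 100 random lists the size of the combined list, 4 passed it for arm share. A planted overlap of 41.4% of 1066 peaks was found as 42.8%, and a planted arm share of 62.5% among 2566 peaks as 62.7%. Simulated peaks were placed independently, without the clusters of the real lists, so the error rate on clustered peaks was not measured. Tests of differences between arm shares and of chromosome ends were not simulated. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.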

Results

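MSH-5 is a meiosis-specific MutS homologue that works with HIM-14/MSH-4 on recombination intermediates that become crossovers. DNA recovered with an antibody against MSH-5 was mapped in fem-2(b245) adults, labelled as hermaphrodites grown at 20 °C. These adults carry a temperature-sensitive allele of a gene for male sexual fate. Hermaphrodites carry a pair of X chromosomes. The question open to the data is where along the chromosomes the antibody enriched DNA, and how well the 2 ChIP libraries gave the same places. Replicate 1 had 1066 peaks, replicate 2 had 1620, and the combined list had 3271. The median peak was 509 bp wide in replicate 1, 348 bp in replicate 2 and 267 bp in the combined list. Nuclear peaks covered 0.888%, 0.902% and 1.43% of the chromosomes, respectively. The number of reads behind the lists is unknown.

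Most of the MSH-5 ChIP peaks with the highest scores in the combined list lay on X. Of the 10 best-scored combined peaks found in both replicates, 9 were on X and 1 was on chromosome V. Of the 41 combined peaks with a score above 100, 26 were on X and 15 on the autosomes, and all 41 were found in both replicates. The series has no ChIP libraries besides these 2, so presence in both replicate lists is not independent support for a combined peak. The 26 X peaks ran from 0.410 to 17.5 Mb, with a median spacing of 0.626 Mb (0.00121 to 1.63) and a median width of 1307 bp, and 10 of them lay in the left 25% of the chromosome. The closest neighbours lay less than the median width apart, so the 26 peaks are not shown to be as many separate sites. The threshold of 100 was chosen after seeing the data.

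The best-scored site spanned 2996202 to 2997788 on X, with a score of 205.23 in the combined list. It scored 3100 in replicate 1 and 3100 in replicate 2. The site at 806305 to 807127 scored 199.96, with scores of 2802.69 in replicate 1 and 2569.96 in replicate 2. A cluster of sites on the left of X held the peaks at 1344464 to 1345548, 1389011 to 1390266, 1503263 to 1505235 and 1626466 to 1627822. Their combined scores were 177.12, 183.28, 199.96 and 190.48, and each scored 3100 in both replicates. Further X sites spanned 4208250 to 4210030 with a score of 185.24, 7181380 to 7182133 with a score of 177.65 and 14524871 to 14526977 with a score of 188.27. The only autosomal site among the best 10 spanned 9546042 to 9547287 on V, and its combined score was 180.17. It scored 1974.79 in replicate 1 and 2201.07 in replicate 2.

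The best sites of the other autosomes scored lower in the combined list. On IV the best site spanned 11912865 to 11916345 with a combined score of 148.69, and on I it spanned 7656485 to 7659542 with a score of 146.21. Both scored 3100 in each replicate, above the V site in the replicate lists. The best site of II spanned 13819498 to 13820287 with a score of 125.08, and that of III spanned 1925009 to 1925509 with a score of 100.33. The II site scored 397.03 in replicate 1, at rank 290 of 1066, and 1433.01 in replicate 2, at rank 64 of 1619 nuclear peaks. The III site scored 689.46 in replicate 1 and 1242.28 in replicate 2.

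**Figure D1:**
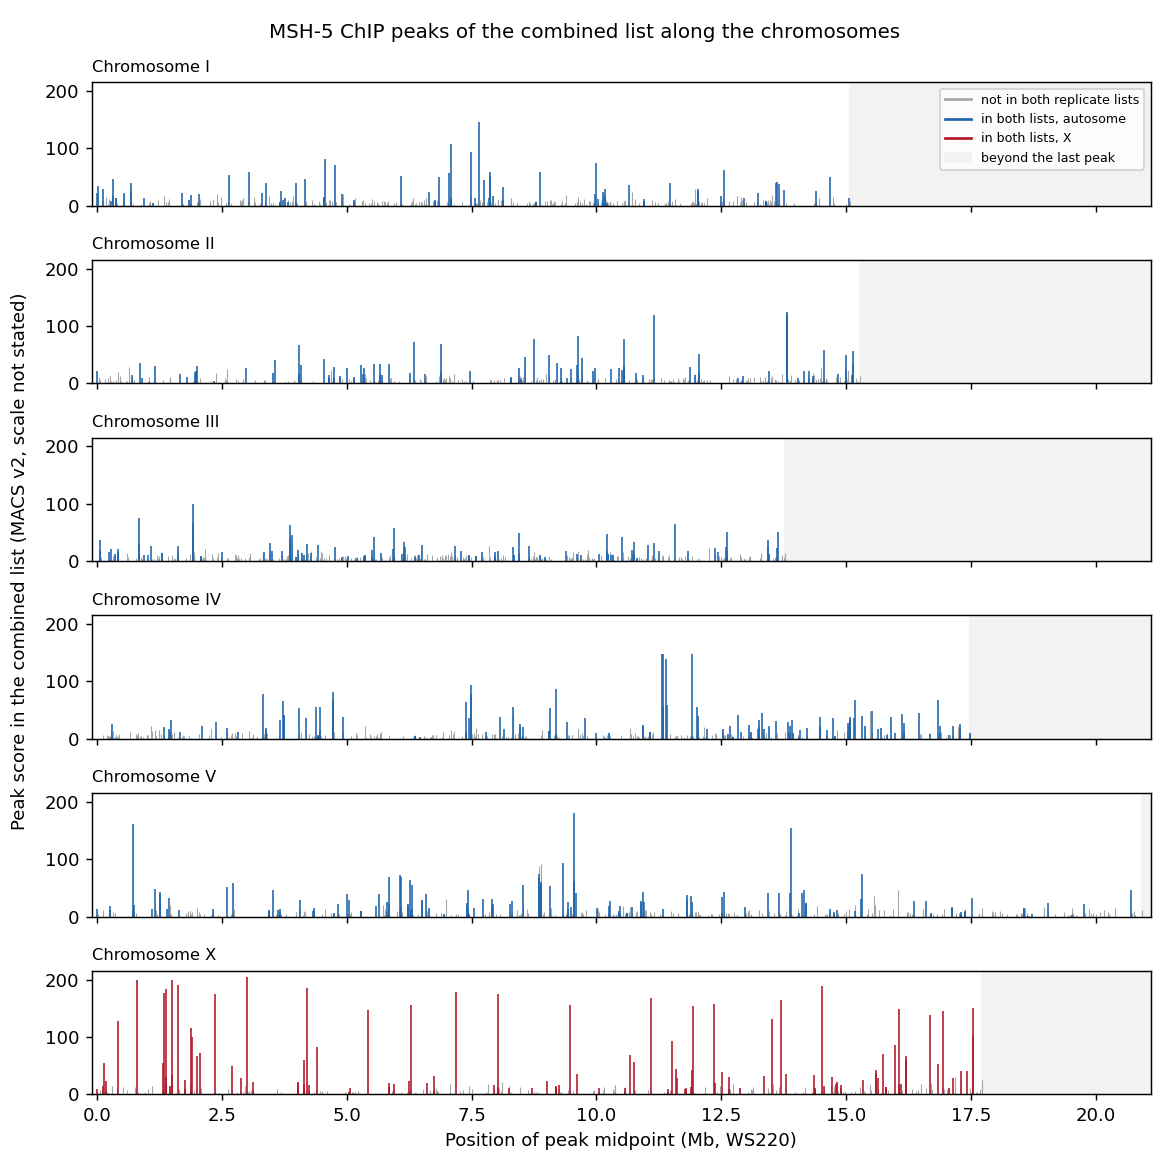
Peaks of the combined list along the 6 chromosomes. The x axis is the peak midpoint in Mb (WS220), the y axis is the deposited score, and each vertical line is 1 peak. Grey lines are peaks not found in both replicate lists, and blue (autosomes) and red (X) lines are peaks found in both. The 26 tall X lines above a score of 100 are spread over the chromosome, against 15 on the autosomes.

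X held fewer peaks than its length would give in the combined list, while it was over-represented at the top of the score range. It had 484 of 3269 nuclear peaks, or 14.8% (95% interval 13.6 to 16.1), against 17.7% of the length (exact binomial test, two-sided, adjusted p = 2.6e-05 over 6 chromosomes). Among the 100 best-scored peaks, 37.0% were on X (27.6 to 47.2), against 14.1% of the remaining 3169 (Fisher's exact test, two-sided, p = 2.2e-08). The number of best-scored peaks, chosen after seeing the data, sets this share: it was 76% among the best 25, 56% among the best 50 and 24% among the best 200. In replicate 1 the best 100 held 33 X peaks, and X had 13.9% of the rest (Fisher's exact p = 4.5e-06). In replicate 2 it held 31 of the best 100 and 16.5% of the rest (Fisher's exact p = 0.00056). The low X share over all peaks did not pass the test in either replicate: it was 15.7% in replicate 1 (exact binomial p = 0.092) and 17.4% in replicate 2 (exact binomial p = 0.82). Among combined peaks found in both replicates it was 18.2%, above the share of length (exact binomial p = 0.70).

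**Figure D2:**
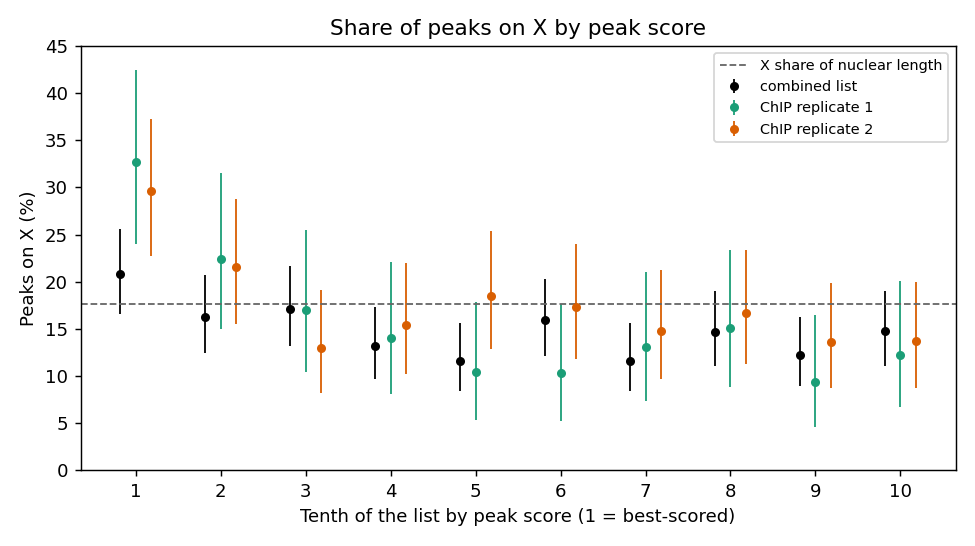
Share of peaks on X by score. The x axis gives 10 groups of nearly equal size per list, from best-scored (1) to lowest (10), the y axis the percentage of peaks on X, points the 3 lists, bars exact 95% intervals and the dashed line the X share of length (17.7%). The best-scored group has 20.8% on X in the combined list, 32.7% in replicate 1 and 29.6% in replicate 2. The interval of the combined list, 16.5 to 25.6, includes the dashed line, and those of the replicates lie above it.

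Among the autosomes, chromosome III had the most combined peaks per Mb and V the fewest. III had 583 combined peaks, or 42.3 per Mb, and 17.8% of peaks against 13.7% of the length (exact binomial test, adjusted p = 3.7e-10). V had 27.5 peaks per Mb and 17.6% of peaks against 20.9% of the length (exact binomial test, adjusted p = 1.1e-05). II held 16.7% of peaks against 15.2% (exact binomial test, adjusted p = 0.027), whereas I with 33.0 peaks per Mb and IV with 33.3 did not pass the test. The excess on III and II and the deficit on V were not past the threshold in either replicate list: III had 15.9% of replicate 1 peaks (exact binomial adjusted p = 0.10) and 15.4% of replicate 2 peaks (exact binomial adjusted p = 0.18). In replicate 1, I was below its share of length at 12.01% of peaks (exact binomial adjusted p = 0.032) and IV above it at 20.5% (exact binomial adjusted p = 0.033), and no chromosome passed in replicate 2.

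Crossovers in this species are more frequent on the chromosome arms than in the centres, so the position of MSH-5 peaks was compared between both. In the combined list 1512 of 3269 peaks, or 46.3% (44.5 to 48.0), lay on the arms, the outer 25% of the length at either side. This was not distinguishable from the 50% of an even spread (circular-shift permutation test, two-sided, p = 0.060). The replicates lay on opposite sides of 50%. Replicate 1 had 54.1% of its peaks on the arms (permutation p = 0.19) and replicate 2 had 43.6% (permutation p = 0.033). The difference of 10.5 percentage points between them was larger than shifts of both lists together gave (permutation p = 0.00011). Shared peaks, the same places counted in each list, had nearly even shares over all chromosomes, 50.5% counted in replicate 1 and 50.1% counted in replicate 2. Combined peaks found in both replicates, another set of intervals, had 47.6% on the arms over all chromosomes (permutation p = 0.44). In that set the arm share was 62.5% on X (permutation p = 0.055) and 44.3% on the autosomes (permutation p = 0.074). Peaks of replicate 1 alone had 61.1% on the arms and those of replicate 2 alone 36.8%.

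In the combined list the arm share was higher on X than on the autosomes with the arms as defined, but not distinguishably so with a narrower centre. On X, 268 of 484 combined peaks lay on the arms, or 55.4% (50.8 to 59.9), and on the autosomes 1244 of 2785, or 44.7% (42.8 to 46.5). The difference was 10.7 points in the combined list (permutation p = 0.00102). It was 13.3 points in replicate 2 (permutation p = 0.00088) and 12.5 points in replicate 1, where it did not pass the test (permutation p = 0.27). With a narrower centre, which leaves 66.7% of the length to the arms, the combined list had 66.9% of X peaks and 63.9% of autosomal peaks on the arms, and the difference of 3.03 points did not pass (permutation p = 0.35). Taken alone, the autosomes lay below an even spread in the combined list (permutation p = 0.014), and the single chromosomes did not pass after adjustment there. The autosomal share did not pass with the better-scored 50% of the peaks, at 46.2%, with peaks found in both replicates, at 44.3%, or with a narrower centre. In replicate 1 it was 52.2% (permutation p = 0.53). The X share did not pass in the combined list (permutation p = 0.060, adjusted p = 0.18 over 6 chromosomes), although its counting interval lay above 50%. It was 54.6% in replicate 2 (permutation adjusted p = 0.086) and 64.7% in replicate 1, the only list in which it passed after adjustment (permutation adjusted p = 0.032).

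**Figure D3:**
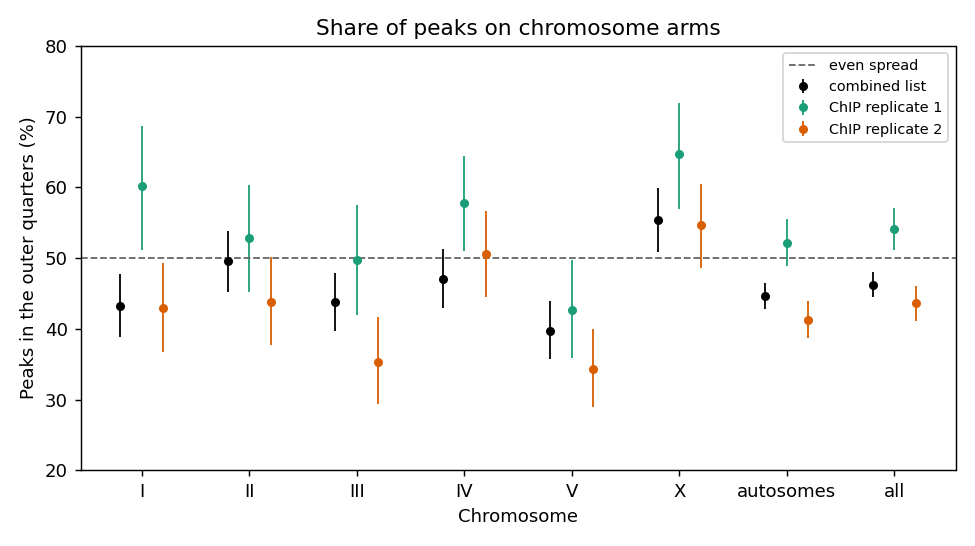
Share of peaks on chromosome arms. The x axis gives the chromosomes, the 5 autosomes together and all 6, the y axis the percentage of peak midpoints in the outer 25% at either side (axis from 20 to 80%), points the 3 lists, bars exact 95% intervals and the dashed line an even spread. Over all chromosomes replicate 1 is at 54.1% and replicate 2 at 43.6%.

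The 2 ChIP replicates shared many more sites than chance gives. Of the replicate 1 peaks 701, or 65.8% (62.8 to 68.6), overlapped a replicate 2 peak, against 1.95% under circular shifts (permutation p = 1e-05, the smallest the shifts can give). Of the nuclear replicate 2 peaks 829 of 1619, or 51.2% (48.7 to 53.7), overlapped a replicate 1 peak, against 1.39% (permutation p = 1e-05). Sharing went with score. In replicate 1, 94.0% of the best-scored 25% of peaks was shared and 36.1% of the lowest-scored 25%, and in replicate 2 these shares were 86.2% and 26.2%. Shared peaks were also wider, with a median of 627 bp against 366 bp in replicate 1 and 484 bp against 274 bp in replicate 2. Over the 857 overlapping pairs of peaks, the scores of the replicates had a Spearman rho of 0.42 and a Pearson r of 0.53. A peak that overlapped several peaks of the other list entered several of these pairs. In 542 pairs, with each peak in 1 pair only, the overlap covered at least 0.5 of each peak, and rho was 0.78. These are correlations across peaks of 2 libraries, and peaks are not independent replicates.

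Some high-scoring places were found in 1 replicate list alone. In replicate 2, peaks on V at 8849978 to 8850595, 8892106 to 8892745 and 8895242 to 8895927 scored 1507.18, 1335.57 and 1389.41, above 96.4%, 95.6% and 95.9% of that list, with no replicate 1 peak within 500 bp. In replicate 1, a peak on V at 15567075 to 15570162 scored 2302.91 and one on X at 289831 to 295382 scored 1592.36, above 94.5% and 92.0% of that list, with no replicate 2 peak within 500 bp.

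The combined list held nearly all replicate peaks and many places that neither replicate list had. It overlapped 94.0% of replicate 1 peaks (92.4 to 95.3) and 90.0% of replicate 2 peaks (88.4 to 91.4). Of its 3269 nuclear peaks 748, or 22.9%, were found in both replicates, 330 in replicate 1 only, 631 in replicate 2 only and 1560, or 47.7% (46.0 to 49.4), in neither. Peaks found in neither were narrow and low, with a median width of 207 bp and a median score of 4.65, against 616 bp and 19.3 for peaks found in both. Peaks found in both made up 48.8% of the bases the list covers. In the best-scored 25% of the combined list 65.2% were found in both replicates and 4.28% in neither, and in the lowest-scored 25% 5.51% and 78.7%.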

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

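A single result was singled out here, because it lies on a chromosome that no comparison used, and its test was chosen after the result was seen. Replicate 2 had a peak over mitochondrial DNA from position 1 to 13452 with a score of 3100, while replicate 1 had no mitochondrial peak. This score is the tied value of 27 peaks in the replicate 2 list. It does not show weaker enrichment than that list's highest score of 3105.66. The combined list had 2 mitochondrial peaks, from 1 to 10526 with a score of 15.08 and from 10729 to 13297 with a score of 17.31. A peak that runs over nearly the whole molecule does not mark a site within it. A candidate explanation is the high and variable copy number of mitochondrial DNA in the ChIP relative to its input, and it cannot be told apart from enrichment by the antibody, because the coverage of the input libraries was not analysed here and only the peak score of 3100 speaks to it. No biological explanation was tested.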

How the results depend on the processing

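The tests of the best-scored peaks, of left ends, of spacing, of the arm share of X and autosomes apart and of differences in arm share were chosen after the data were seen. No paired analysis was possible because the input libraries, which share their replicate numbers with the ChIP libraries, enter no test and the 2 ChIP replicates are not compared under 2 conditions. Of 59 alternatives over 13 results, 42 kept direction and side of the threshold, or their value. Replicate overlap, the X share of the best-scored peaks, the arm difference between replicates, peaks at left chromosome ends and spacing kept direction and side under all alternatives run, but sizes moved. The shared percentage of replicate 2 fell from 51.2% to 33.5% with an overlap of 0.5 of both peaks, the X share of the best-scored peaks ran from 24% (best 200) over 56% (best 50) to 76% (best 25), and gaps under 2 kb fell from 35.8% to 21.7% with the better-scored 50%. Requiring an overlap of 0.5 of both peaks raised the Spearman rho of scores from 0.42 to 0.78 and lowered the share of combined peaks found in at least 1 replicate from 52.3% to 37.3%, and the better-scored 50% raised that share to 77.5%. The X share of 14.8% was 15.7% to 17.4% in the single replicate lists, no longer past the threshold, 17.1% as a share of covered bases, and 18.2%, above the share of length, for peaks found in both replicates. The arm share of 46.3% was 43.6% to 54.1% in the single lists, past the threshold in replicate 2 alone and reversed in replicate 1. For the autosomes, 44.7% became 41.3% to 52.2% in the single lists, reversed in replicate 1, and it did not pass with the better-scored 50% (46.2%), peaks found in both replicates (44.3%) or a narrower centre (63.9%, against 66.7% of length). For X, 55.4% became 54.6% to 64.7% in the single lists, past the threshold in each before adjustment over the 6 chromosomes and in replicate 1 alone after it, and with a narrower centre it was 66.9%, near the 66.7% of length (permutation p = 0.95). The difference of 10.7 points between X and autosomes was 12.5 to 13.3 in the single lists, not past the threshold in replicate 1, 3.03 with a narrower centre, not past it, 16.6 with the better-scored 50% and 18.2 for peaks found in both replicates. Smaller lists have fewer peaks to test, and for the reversals and other changes the cause was not tested. Counts of peaks at gene starts, in gene lists and at tRNA genes were not run. Read depth is unknown, so a peak missing from a list is not shown to be absent.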

Other observations

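The tests of chromosome ends and of spacing were chosen after the data were seen. The left ends of the chromosomes, where telomere repeats lie, carried MSH-5 ChIP peaks. Each replicate list had a peak within 1 kb of position 1 on all 6 chromosomes, against 0.109 chromosomes in replicate 1 and 0.133 in replicate 2 under circular shifts (permutation p = 1e-05 in each, the smallest the shifts can give). The combined list had such a peak on 4, namely I, II, V and X (permutation p = 5e-05). The peak at the left end of I, from 1 to 510 in replicate 2, scored 1906.94, above 97.1% of that list, and in replicate 1 it ran from 1 to 521 and scored 1059.47, above 89.2%. Right ends were not tested, because the chromosome lengths were taken from the last peaks. The widest nuclear peak was at the right end of I in all 3 lists, a part of the chromosome that carries the ribosomal DNA repeats. It ran from 15060186 to 15071361 in replicate 1 with a score of 3100 and from 15060282 to 15071351 in replicate 2 with a score of 1375.92. Repeats are hard to place with short reads, and the input coverage of the left ends and of this part of I was not analysed here. The shifts test only the position of peaks, so enrichment by the antibody at these ends cannot be told apart from misplaced repeat reads.

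Peaks lay in clusters. In the combined list 35.8% of the gaps between neighbouring peaks were under 2 kb, against 7.79% under random placement (permutation p = 0.001, the smallest that 1000 placements can give), and the shares were 25% in replicate 1 and 30.5% in replicate 2. The placements put each peak down on its own, so broad enrichment cut into several peaks would also give short gaps. Whether neighbouring peaks are separate sites or parts of 1 site was not tested. The densest 50 kb window, on I from 10173069 to 10219069, held 22 combined peaks with a median score of 4.46, of which 7 were found in replicate 1 and 9 in replicate 2. On IV the right 25% held more replicate peaks than the left 25%, 89 against 37 in replicate 1 and 97 against 41 in replicate 2. The combined list had 143 against 131 on IV. II was also heavier on the right, with 177 against 94 in the combined list. In replicate 1 it had 54 against 40, and in replicate 2 it had 73 against 41. Left against right was not tested.

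All tests of explanations in the last paragraphs were chosen after the pattern they weigh was seen, and that of a single library also after its own value was known. The excess of X among the best-scored peaks is not accounted for by the splitting of single sites into several peaks, since with peaks within 10 kb merged X had 39.0% of the best 100 regions (29.4 to 49.3). A single deviating library is argued against by the lower of the 2 replicate values, 31% (22.1 to 41.03), which is above the 17.7% of length. Limiting peak width to 500 to 2000 bp left 618 peaks. Of these, X had 29.9% of the best-scored 25% and 16.6% of the rest (odds ratio 2.14, Fisher's exact p = 0.00066). Widths were not matched within that range, so a contribution of width to the excess cannot be excluded. As a hypothesis, the strong X sites may be places that many chromatin proteins occupy or crosslink to on X in hermaphrodites, such as the recruitment sites of the dosage compensation complex. That was not tested, since it needs a site list in the same build and a control antibody, and sequence effects, antibody specificity and input coverage stay open. A factor common to all X peaks stays open too: the median X score was 6.92 in the combined list, against 6.05 to 6.36 on the autosomes, 119.9 in replicate 2, against 94.12 to 125.98, and 313.51 in replicate 1, against 111.76 to 195.33. The lists differ in this, and they leave out peaks under the caller's threshold.

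The replicates differed in arm share, 54.1% against 43.6%. Weaker peaks in the longer list of replicate 2 did not account for all of this difference. The best 1066 peaks of replicate 2 had 45.5% on the arms (42.5 to 48.5), below replicate 1. That interval covers counting only and takes clustered peaks as independent. With the better-scored part of each list, the shares were 54.6% and 46.7%, a difference of 7.87 points (permutation p = 0.0019). The difference over all peaks was 10.5 points, so a partial contribution of weaker peaks stays open. Clustered peaks counted several times did not account for all of the difference either. Merged within 2 kb, the shares were 52.8% and 43.7%, 9.11 points apart (permutation p = 0.00029). A difference between libraries in chromatin preparation or depth may stand behind it and stays open, because the labels give no batch and the lists no reads. No biological explanation was tested, since both replicates have the same labels.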
